A study of Nostoc sp. PCC 7120 = FACHB-418 with 20 samples.

How the data were processed

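Total RNA from Nostoc sp. PCC7120 was measured on 20 custom Agilent arrays with 1 colour (Cy3), in 11 groups of strain and nitrogen status. Per the labels' protocols, cells grew in BG11 medium at 30 °C with 6 mM ammonium chloride or with atmospheric nitrogen, RNA was prepared with hot phenol, and 2 µg of it was labelled without cDNA synthesis, so that the arrays read each strand apart. Per the file headers, the deposited scanner files hold spot intensities from Agilent Feature Extraction 10.7.3.1, among them a mean signal, a local background, and a processed signal with background subtracted and low values replaced, not normalized between arrays. The deposited value table holds log2 values made by the authors with limma, per the submitters' processing notes. Their medians outside controls lay close over arrays, at 9.18 to 9.21, as after quantile normalization. The files also hold flags of 0 or 1 per spot, per the file headers, of which the flag for signals well above background was used.

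The processed intensities of 61537.0 spots outside controls were taken as log2 and set against the 75th percentile of each array. Spots of 1 probe were averaged, as were probes of 1 feature, over 55231 probes and 19836 features (6079 sense gene features, 9372 intergenic, 4379 antisense and 6 small RNAs). A probe entered when well above background on at least 2 of the 20 arrays, which left 17397 features and 5882 genes. Gene names came from the array file and, for 5835 gene features matched by name or position, from the RefSeq annotation of assembly ASM970v1. Locus tags of 3620 features were given by both sources and differed in 0. Coordinates are those of the array file. The nifD feature was matched by the start of the gene, since its name is cut short, and it is in no list. A gene counts as protein-coding when the annotation says so or when it has a locus tag and no match.

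All 20 arrays entered 1 limma fit (limma 3.58.1 in R 4.3.3) with a coefficient per group and moderated variances, so that groups of 2 share an estimate of spread and groups of 1 array are assumed to vary like the others. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 was used for reading the files and drawing. Each later time was compared with 0 h in each strain, the mutant with WT at 0 h, and the change of WT with that of the mutant. Benjamini-Hochberg adjustment was over all features of a comparison, with a threshold of 0.05. The steps from 12 h to 24 h were planned, and the step from 6 h to 12 h was added after the data were seen. The 8 h array was tested against 0 h with the spread of the replicated groups. By the design set beforehand, the array without combined nitrogen and that after ammonium addition have no test, and their counts are of genes at least 2-fold apart. Folds written as at least are set against the lowest signal well above background where a group is under it, while log2 changes use the signals as they are.

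The groups, the comparisons, the named genes, the gene lists and most alternatives were chosen before the data were examined. The 15 lists are nitrogenase, glycolipid layer, polysaccharide layer, Dev exporter, differentiation regulators, heterocyst respiration (oxidases, flavodiiron proteins and uptake hydrogenase), nitrogen assimilation, phycobilisome, photosystem II, photosystem I, carbon fixation, ATP synthase, oxidative pentose phosphate pathway, ribosomal proteins and chaperones. Heterocyst lists and those for phycobilisome, photosystem II and carbon fixation serve as markers of the heterocyst and the vegetative cell. Chaperones (17 genes) were found by symbol, as the annotation has no product names. Lists were tested with camera against the other sense gene features, at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. The use of sense gene features as the universe was settled while the analysis was written.

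Named genes are, per comparison, those with the 10 (WT at 6, 12 and 24 h) or 5 highest and lowest changes among called protein-coding genes whose arrays do not overlap between groups (no such condition for differences of response), up to 4 called members of each list with the largest change, and a set of known genes of nitrogen control, fixation and photosynthesis. The text gives part of each set. For arrays with no test the 10 highest and lowest genes and features were taken. Genes in the highest and lowest places thus have each array of a group on 1 side of each array of the other.

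Alternatives were normexp background correction (offset 50) with quantile normalization, quantile normalization of the processed signal, the array median, the deposited values, 2 other filters, slide as a random or fixed block, the replicate number as a block, fits of the compared groups alone, a variance trend with robust moderation, the median or the brightest probe of a gene, a 2-fold threshold and leaving out each array. The check that called genes at least 2-fold apart kept their direction in each scaling was chosen after the shares of higher calls were seen. The fit was tested on simulated data with the real spread of each of 17397 features, independent noise, no slide effect and few changed features. It thus does not measure errors from slides or where many features change, as in the real comparisons. For WT at 24 h, 19 of 67 features changed by 1.5-fold were recovered, 45 of 67 at 2-fold and 64 of 66 at 4-fold, with 5 unchanged features among 133 calls. For the difference of response at 24 h, 3 of 67, 25 of 67 and 51 of 66 were recovered, with 2 unchanged among 81 calls. No sample was left out.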

Results

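Transcript levels were measured on 20 one-colour arrays of Nostoc sp. PCC7120, a filamentous cyanobacterium in which some cells become nitrogen-fixing heterocysts when combined nitrogen is removed. The wild type (WT) was sampled in ammonium medium (0 h, 3 arrays) and at 6 h (2), 8 h (1), 12 h (2) and 24 h (2) after removal of ammonium. A mutant of hetR, the gene of a regulator needed for heterocyst differentiation, was sampled at 0, 6, 12 and 24 h with 2 arrays each. There was 1 array of WT growing without combined nitrogen and 1 array taken 8 h after ammonium was given to such cells. Levels are log2 signals relative to the 75th percentile of each array, and changes are log2 differences ± their limma standard error. Where a group is below detection, they use signals under the detection limit and their size is uncertain. Calls are at a Benjamini-Hochberg adjusted p under 0.05 over all features, and where 1 count of a gene list is given, the count adjusted over the list alone is the same. Replicates of a group correlated across genes, which are not independent replicates, at Pearson r from 0.978 to 0.991. The labels do not state that the repeated experiments were separate cultures, so the p-values measure the spread between these arrays, whose number limits the precision.

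Between 31.8% and 46.7% of probes were well above background on slide 1, which held the 6 h arrays and the 0 h arrays other than WT replicate 3. On slide 2, which held every 12 h and 24 h array, the share was 53.8% to 71.1%. Comparisons of 12 h and 24 h with 0 h are therefore confounded with slide. Their changes fell with level, at slopes of -0.15 to -0.25, and the part of this in list changes was not tested. WT replicate 3 at 0 h and the 8 h array lay on slide 3.

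The hetR transcript was at 2.37 ± 0.12 (SD, n = 3) in WT and 2.26 ± 0.030 (SD, n = 2) in the mutant at 0 h. At 6 h the levels were 3.95 ± 0.026 (SD, n = 2) and 3.22 ± 0.0019 (SD, n = 2), at 12 h 2.78 ± 0.071 (SD, n = 2) and 2.61 ± 0.011 (SD, n = 2), and at 24 h 2.59 ± 0.010 (SD, n = 2) and 1.98 ± 0.090 (SD, n = 2). The 8 h array was at 3.72, WT without combined nitrogen at 2.92 and the array after ammonium addition at 2.18. The labels do not give the site of the mutation, and the 0 h difference was -0.11 ± 0.10, adjusted p = 0.403, so the hetR probes do not check which arrays are of the mutant. The array holds no feature named patS or NsiR1.

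After 6 h without ammonium (2 arrays against 3), transcripts for the polysaccharide layer of the heterocyst envelope rose most in WT. Of 19 polysaccharide genes, 19 were higher, with a median of 6.00 (camera adjusted p = 1.29e-28, adjusted p = 0.0286 with an estimated correlation). The gene alr2827, at 3443322 to 3444350 on the chromosome in the array's own coordinates, rose by 8.20 ± 0.18, adjusted p = 8.99e-11, and was at least 58.8-fold higher when set against the detection limit of the 0 h arrays. Other genes among the 10 highest were asl2052 (8.08 ± 0.24), rfbF (7.95 ± 0.20), lhgO (7.88 ± 0.21) and alr2831 (7.46 ± 0.28). Of 18 differentiation regulator genes, 10 were higher (11 adjusted over the list alone) and 1 lower, with a median of 0.64 (camera adjusted p = 2.22e-05, adjusted p = 0.0286 with an estimated correlation). Among these were all4312 (4.62 ± 0.22), hetP (3.51 ± 0.11) and sigC (2.77 ± 0.18), and patA, which acts on heterocyst pattern, fell (-2.01 ± 0.23). The regulator genes hetR (1.58 ± 0.10, adjusted p = 2.06e-07), hetZ (1.25 ± 0.15, adjusted p = 4.13e-05) and ntcA, the global nitrogen regulator (1.47 ± 0.11, adjusted p = 1.11e-06), also rose. The ABC transporter gene hetC was at 1.35 ± 0.27, adjusted p = 0.00244, but -0.14 with the brightest probe. The gene asr4517 (nblA), whose product starts phycobilisome breakdown, rose by 4.66 ± 0.20, adjusted p = 8.53e-09.

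Of 20 nitrogen assimilation genes, 15 were higher (16 adjusted over the list alone) and 2 lower, with a median of 1.15 (camera adjusted p = 0.000114, adjusted p = 0.0931 with an estimated correlation). Among them, glnA for glutamine synthetase rose by 0.48 ± 0.11, adjusted p = 0.00489, while asl2329, for an inactivating factor of that enzyme, fell (-4.12 ± 0.22). The value of nirA, for nitrite reductase, was 1.41 ± 0.41, adjusted p = 0.0201, but -0.95 with the brightest probe. The Dev exporter carries glycolipid to the envelope. Of 3 Dev exporter genes, 3 were higher, with a median of 1.53 (camera adjusted p = 0.00132, adjusted p = 0.0948 with an estimated correlation). Of 9 heterocyst respiration genes, 4 were higher, with a median of 0.64 (camera adjusted p = 0.00132, adjusted p = 0.286 with an estimated correlation). The 4 higher respiration genes were alr2514, alr2515, alr2516 and all0178. Of 17 nitrogenase genes, 4 were higher and 1 lower, with a median of 0.20, against -0.058 with normexp with quantile normalization and -0.060 with the authors' deposited values (camera adjusted p = 0.0453, adjusted p = 0.615 with an estimated correlation). Values of nifH (-0.57 ± 0.59, adjusted p = 0.507), nifB (0.20 ± 0.23, adjusted p = 0.569) and the excisase gene xisA (0.30 ± 0.25, adjusted p = 0.395) did not pass the test. Of 18 glycolipid genes, 0 were higher and 1 lower, with a median of 0.042 and mean of -0.031 (camera adjusted p = 0.659).

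Genes of light harvesting and growth fell over the same 6 h. Of 21 phycobilisome genes, 21 were lower, with a median of -1.82 (camera adjusted p = 1.30e-15, adjusted p = 0.101 with an estimated correlation). The phycoerythrocyanin genes led, with pecE (-5.55 ± 0.32), pecB (-4.90 ± 0.31), pecC (-4.86 ± 0.24) and pecA (-4.82 ± 0.22), and cpcB for phycocyanin was at -1.57 ± 0.18. Of 23 ribosomal protein genes, 22 were lower (23 adjusted over the list alone), with a median of -1.60 (camera adjusted p = 1.65e-14, adjusted p = 0.165 with an estimated correlation). Of 9 ATP synthase genes, 9 were lower, with a median of -0.85 (camera adjusted p = 6.97e-05, adjusted p = 0.265 with an estimated correlation). Of 14 photosystem II genes, 11 were lower and 1 higher, with a median of -0.78 (camera adjusted p = 0.000758, adjusted p = 0.265 with an estimated correlation). The higher member was psbA alr3742 (1.37 ± 0.30, adjusted p = 0.00392), and psbB was at -0.78 ± 0.11, adjusted p = 0.000133. Of 8 photosystem I genes, 8 were lower, with a median of -0.68 (camera adjusted p = 0.00132, adjusted p = 0.286 with an estimated correlation). Of 17 carbon fixation genes, 10 were lower, with a median of -0.59 (camera adjusted p = 0.00324, adjusted p = 0.265 with an estimated correlation). The RuBisCO gene rbcL fell (-1.25 ± 0.12). Of 17 chaperone genes, 13 were lower and 1 higher, with a median of -0.48 (camera adjusted p = 0.00322, adjusted p = 0.285 with an estimated correlation). Of 5 pentose phosphate genes, 0 were higher, with a median of -0.19 (camera adjusted p = 0.659). The lowest gene of all was asr1328 (-6.33 ± 0.14). Of 5882 genes, limma called 857 higher and 1376 lower, so that 38.4% of the calls were higher. This share ran from 18.3% with normexp with quantile normalization to 62.4% with the array median over the other scalings, and the median of all genes from -0.22 to 0.10. In each scaling, all of the 672 called genes at least 2-fold apart kept their direction, and a fixed slide block gave calls for 39.3% of genes. Scalings that move all genes alike could not have turned these, here or in the counts below.

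On the single WT array at 8 h the envelope genes were high. Its p-values rest on the spread of the replicated groups, since 1 array has none, and a fit of this array and the 0 h arrays alone called 249 genes in place of 1906. In that fit camera, run so after the data were seen, called 14 of the 14 lists called with all arrays, and 0 of them with an estimated correlation. Polysaccharide genes had a median of 5.51, with 19 higher of 19 (camera adjusted p = 1.13e-26, adjusted p = 0.0353 with an estimated correlation). Dev exporter genes had a median of 3.92, with 3 higher of 3 (camera adjusted p = 2.58e-05, adjusted p = 0.0372 with an estimated correlation). Differentiation regulator genes had a median of 1.08, with 13 higher and 1 lower of 18 (camera adjusted p = 3.07e-07, adjusted p = 0.0123 with an estimated correlation). Heterocyst respiration genes had a median of 3.32, with 9 higher of 9 (camera adjusted p = 3.33e-08, adjusted p = 0.0994 with an estimated correlation). Glycolipid genes had a median of 1.36, with 13 higher of 18 (camera adjusted p = 2.28e-07, adjusted p = 0.153 with an estimated correlation). Nitrogenase genes had a median of 1.68, with 10 higher of 17 (camera adjusted p = 7.08e-07, adjusted p = 0.197 with an estimated correlation). Called members of the nitrogenase list were nifT (4.74 ± 0.44), asr1408 (4.35 ± 0.26) and nifV (3.72 ± 0.29), and nifH was at 2.78 ± 0.75, adjusted p = 0.017. Phycobilisome genes had a median of -2.12, with 21 lower of 21 (camera adjusted p = 1.06e-17, adjusted p = 0.0831 with an estimated correlation). The test called 870 of 5882 genes higher and 1036 lower, 45.6% of the calls being higher. Over the other scalings the share lay from 18.9% with normexp with quantile normalization to 66.0% with the 75th percentile over probes detected on all arrays, and the median of all genes from -0.27 to 0.19. Direction was kept in each scaling by all of the 850 called genes at least 2-fold apart, and with a fixed slide block, which sets this array against WT 0 h replicate 3 alone, 25.8% of genes were called.

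By 12 h in WT (2 arrays against 3), transcripts for nitrogen fixation and for the glycolipid layer had risen. The 17 nitrogenase genes included 17 higher, at a median of 5.25 (camera adjusted p = 9.49e-15, adjusted p = 0.0817 with an estimated correlation). The nitrogenase structural genes nifH, at 1713396 to 1714283 on the chromosome (7.24 ± 0.59, adjusted p = 1.12e-06), nifD (7.59 ± 0.43) and nifK (7.15 ± 0.23) rose, as did fdxH for the heterocyst ferredoxin (6.72 ± 0.22). Set against the detection limit, nifK was at least 37.2-fold and nifD at least 52.0-fold higher. The 18 glycolipid genes included 17 higher, at a median of 4.15 (camera adjusted p = 4.48e-12, adjusted p = 0.0817 with an estimated correlation). Examples were hglE for a glycolipid synthase (5.64 ± 0.20) and hetM (5.43 ± 0.34). The 9 heterocyst respiration genes included 9 higher, at a median of 5.14 (camera adjusted p = 8.00e-08, adjusted p = 0.0985 with an estimated correlation). These include the oxidase gene alr2514 (5.79 ± 0.38) and all0178 for a flavodiiron protein (5.45 ± 0.20). The 3 Dev exporter genes included 3 higher, at a median of 3.81 (camera adjusted p = 0.000568, adjusted p = 0.0817 with an estimated correlation). The 19 polysaccharide genes included 19 higher, at a median of 3.55 (camera adjusted p = 9.49e-15, adjusted p = 0.0817 with an estimated correlation).

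The 18 differentiation regulator genes included 11 higher and 1 lower, at a median of 0.58 (camera adjusted p = 0.000269, adjusted p = 0.0817 with an estimated correlation). Among them, alr5358 (5.06 ± 0.22), all4312 (4.16 ± 0.22) and patB (2.15 ± 0.18) rose, and patA was at -2.01 ± 0.23. The values of hetR were 0.41 ± 0.10, adjusted p = 0.00417, of hetC 1.48 ± 0.27, adjusted p = 0.00073, of hetP 1.37 ± 0.11, adjusted p = 7.74e-07, of hetZ 0.44 ± 0.15, adjusted p = 0.0235 and of ntcA 0.071 ± 0.11, adjusted p = 0.621. Nitrogen assimilation genes had a median of 0.57, with 13 higher and 4 lower of 20 (camera adjusted p = 0.0335, adjusted p = 0.176 with an estimated correlation). The nitrate transport gene nrtA alr0608 was at 4.01 ± 0.53 and nirA at 3.72 ± 0.41, adjusted p = 1.45e-05, but -0.34 with the brightest probe. Values were 4.70 ± 0.20 for nblA, 0.32 ± 0.11, adjusted p = 0.0266 for glnA and 0.73 ± 0.25, adjusted p = 0.0283 for xisA.

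Light harvesting and growth transcripts were low at 12 h. The 21 phycobilisome genes included 21 lower, at a median of -3.30 (camera adjusted p = 5.62e-15, adjusted p = 0.0817 with an estimated correlation). Ribosomal protein genes had a median of -2.16, with 23 lower of 23 (camera adjusted p = 1.18e-14, adjusted p = 0.0985 with an estimated correlation). ATP synthase genes had a median of -1.76, with 9 lower of 9 (camera adjusted p = 1.05e-06, adjusted p = 0.126 with an estimated correlation). Photosystem II genes had a median of -1.73, with 13 lower and 1 higher of 14 (camera adjusted p = 8.00e-08, adjusted p = 0.0817 with an estimated correlation). Photosystem I genes had a median of -1.34, with 8 lower of 8 (camera adjusted p = 7.17e-05, adjusted p = 0.158 with an estimated correlation). Carbon fixation genes had a median of -1.24, with 13 lower of 17 (camera adjusted p = 6.99e-06, adjusted p = 0.0817 with an estimated correlation). The lowest genes were pecE (-6.11 ± 0.32), asr1328 (-5.98 ± 0.14), pecA (-5.85 ± 0.22) and pecC (-5.72 ± 0.24). Among 5882 genes, 1571 were called higher and 1755 lower (47.2% higher). Other scalings gave shares from 32.5% with normexp with quantile normalization to 72.6% with the 75th percentile over probes detected on all arrays, and moved the median of all genes from -0.25 to 0.34. A random slide block gave calls for 38.2% of genes, and 1349 or more of the 1354 called genes at least 2-fold apart kept their direction in each scaling.

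From 6 h to 12 h, a comparison chosen after the data were seen and confounded with slide, the envelope layers parted. Of 18 glycolipid genes, 18 were higher, with a median of 4.23 (camera adjusted p = 7.22e-15, adjusted p = 0.11 with an estimated correlation). Of 19 polysaccharide genes, 19 were lower, with a median of -2.46 (camera adjusted p = 9.11e-13, adjusted p = 0.11 with an estimated correlation). Of 17 nitrogenase genes, 17 were higher, with a median of 4.86 (camera adjusted p = 3.17e-16, adjusted p = 0.11 with an estimated correlation).

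At 24 h (2 arrays against 3), WT held high nitrogenase transcripts. Nitrogenase genes had a median of 4.88, with 17 higher of 17 (camera adjusted p = 1.25e-15, adjusted p = 0.0939 with an estimated correlation). The highest genes were nifH (7.98 ± 0.59, adjusted p = 7.29e-07), nifK (7.50 ± 0.23), nifD (7.97 ± 0.43) and fdxH (7.14 ± 0.22), and nifB was at 4.82 ± 0.23. Of 9 heterocyst respiration genes, 9 were higher, with a median of 4.27 (camera adjusted p = 1.12e-07, adjusted p = 0.11 with an estimated correlation). Polysaccharide genes had a median of 3.06, with 19 higher of 19 (camera adjusted p = 1.54e-15, adjusted p = 0.0939 with an estimated correlation). Of 3 Dev exporter genes, 3 were higher, with a median of 3.09 (camera adjusted p = 0.000846, adjusted p = 0.0939 with an estimated correlation). Glycolipid genes had a median of 2.52, with 17 higher of 18 (camera adjusted p = 2.61e-09, adjusted p = 0.11 with an estimated correlation). Between 12 h and 24 h, which share slide 2, glycolipid transcripts fell and ribosomal protein transcripts rose. The 18 glycolipid genes included 14 lower (16 adjusted over the list alone), at a median of -1.74 (camera adjusted p = 2.07e-13, adjusted p = 0.126 with an estimated correlation). The 23 ribosomal protein genes included 23 higher, at a median of 1.79 (camera adjusted p = 2.64e-35, adjusted p = 0.113 with an estimated correlation). The 17 nitrogenase genes included 0 lower, at a median of -0.25 (camera adjusted p = 0.18).

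Of 18 differentiation regulator genes, 10 were higher and 3 lower, with a median of 0.68 (camera adjusted p = 0.00287, adjusted p = 0.0939 with an estimated correlation). The values of hetR were 0.22 ± 0.10, adjusted p = 0.085, of hetZ -0.42 ± 0.15, adjusted p = 0.033, of hetC 1.39 ± 0.27, adjusted p = 0.0012, of hetP 0.82 ± 0.11, adjusted p = 6.25e-05 and of ntcA 0.41 ± 0.11, adjusted p = 0.00889. The 20 nitrogen assimilation genes included 5 higher and 6 lower, at a median of 0.0033 (camera tested lower than other genes, adjusted p = 0.704). The value of nirA was 1.88 ± 0.41, adjusted p = 0.00267, but -1.83 with the brightest probe. Of 21 phycobilisome genes, 21 were lower, with a median of -2.93 (camera adjusted p = 7.07e-16, adjusted p = 0.0939 with an estimated correlation). The lowest of these were pecA (-6.67 ± 0.22) and pecB (-6.59 ± 0.31), and nblA was at 3.64 ± 0.20. The 8 photosystem I genes included 8 lower, at a median of -1.53 (camera adjusted p = 4.09e-06, adjusted p = 0.132 with an estimated correlation). The 14 photosystem II genes included 13 lower, at a median of -1.33 (camera adjusted p = 1.12e-07, adjusted p = 0.094 with an estimated correlation). The 9 ATP synthase genes included 9 lower, at a median of -0.91 (camera adjusted p = 5.78e-05, adjusted p = 0.209 with an estimated correlation). Of 23 ribosomal protein genes, 18 were lower (19 adjusted over the list alone), with a median of -0.43 (camera adjusted p = 0.000215, adjusted p = 0.392 with an estimated correlation). Their median was 0.061 to 0.16 with quantile normalizations or the authors' deposited values. Calls were made for 1486 genes in the higher and 1645 in the lower direction out of 5882, or 47.5% higher. Under other scalings that share went from 28.1% with the array median to 75.8% with the 75th percentile over probes detected on all arrays, and the median of all genes from -0.28 to 0.38. With a random slide block the calls covered 34.2% of genes, and 1140 or more of the 1148 called genes at least 2-fold apart kept their direction in each scaling.

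In WT at 24 h, 1632 of 7344 intergenic features were called higher and 2033 lower. Among the highest were 7.57 ± 0.36 at 1711421 to 1713395, beside nifH and not tested apart from it, and 7.45 ± 0.21 at 1691574 to 1691688. Among the lowest was -7.38 ± 0.49 at 616897 to 616971. The small RNA NsiR3 rose at 6 h in WT (7.19, adjusted p = 1.92e-10) and in the mutant (6.36, adjusted p = 2.39e-09). NsiR2 rose at 6 h in WT (3.62, adjusted p = 1.23e-08), with a difference from the mutant's response of 4.06 (adjusted p = 6.32e-07). For NC-27 that difference was 4.44 (adjusted p = 4.45e-08). NsrR1 was lower at 6 h in WT (-1.91, adjusted p = 1.11e-06) and in the mutant (-2.17, adjusted p = 9.80e-07). These small RNAs were named after their values were seen.

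**Figure D1:**
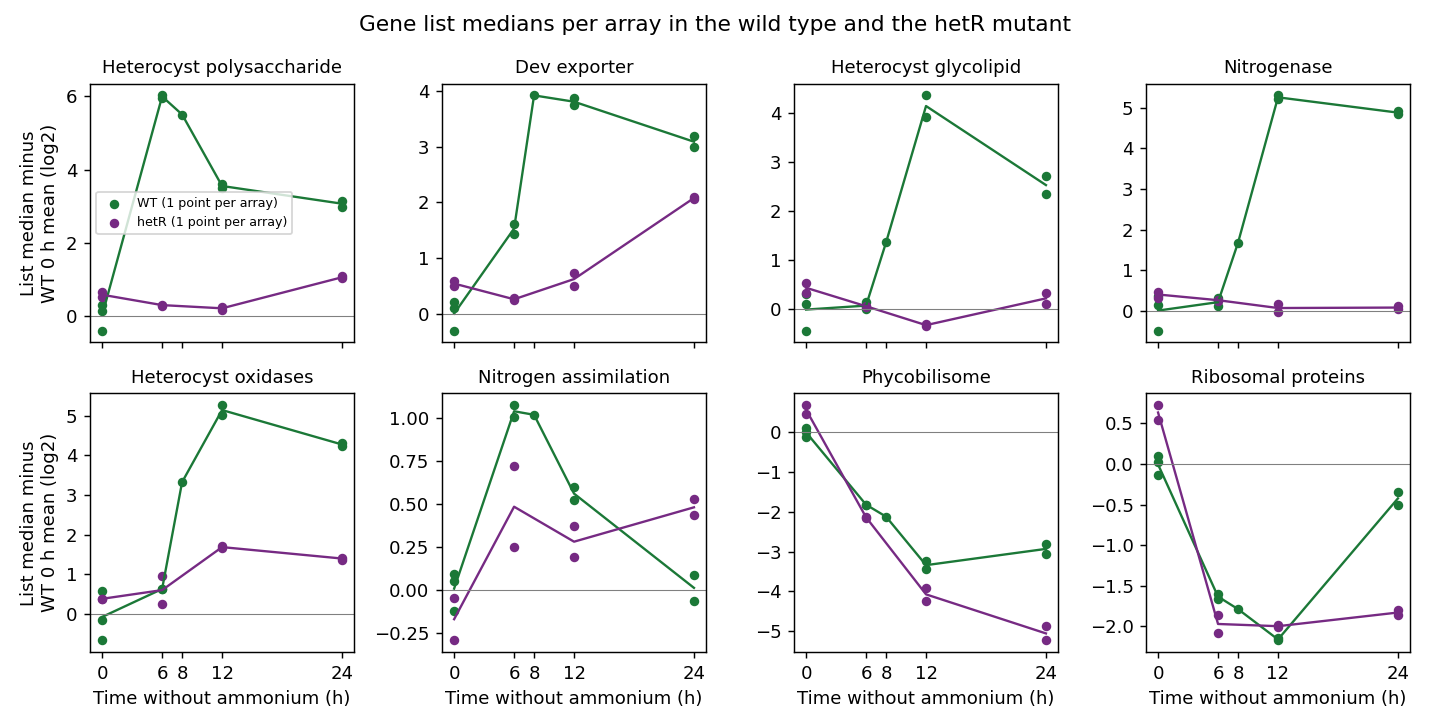
Median log2 value of 8 gene lists on each array (points), relative to the mean of the WT 0 h arrays, against hours without ammonium, with lines through group means of WT and the hetR mutant. The arrays of WT at 6 h have polysaccharide medians of 6.03 and 5.97, those of the mutant 0.30 and 0.28. At 12 h the nitrogenase medians are 5.30 and 5.21 in WT and -0.039 and 0.18 in the mutant.

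In the hetR mutant at 6 h (2 arrays against 2), light harvesting and ribosomal transcripts fell, and polysaccharide and nitrogenase genes were not called as lists. Phycobilisome genes had a median of -2.68, with 21 lower of 21 (camera adjusted p = 1.24e-18, adjusted p = 0.118 with an estimated correlation). Ribosomal protein genes had a median of -2.57, with 23 lower of 23 (camera adjusted p = 1.69e-20, adjusted p = 0.118 with an estimated correlation). Of 9 ATP synthase genes, 9 were lower, with a median of -1.56 (camera adjusted p = 2.01e-07, adjusted p = 0.171 with an estimated correlation). Of 14 photosystem II genes, 13 were lower and 1 higher, with a median of -1.08 (camera adjusted p = 1.14e-06, adjusted p = 0.146 with an estimated correlation). Of 8 photosystem I genes, 8 were lower, with a median of -0.81, against 0.091 with normexp with quantile normalization and 0.071 with quantile normalization and 0.11 with the authors' deposited values (camera adjusted p = 0.000681, adjusted p = 0.341 with an estimated correlation). Of 20 nitrogen assimilation genes, 10 were higher (11 adjusted over the list alone) and 3 lower, with a median of 0.95 (camera adjusted p = 0.000599, adjusted p = 0.118 with an estimated correlation). Differentiation regulator genes had a median of 0.24, with 6 higher (8 adjusted over the list alone) and 2 lower of 18 (camera adjusted p = 0.011, adjusted p = 0.118 with an estimated correlation). Heterocyst respiration genes had a median of 0.21, against -0.024 with the array median, with 3 higher of 9 (camera adjusted p = 0.0872). With all features as camera's universe the adjusted p of respiration was 0.0292, and with an estimated correlation among genes it was 0.721. The 19 polysaccharide genes included 0 higher and 1 lower (0 adjusted over the list alone), at a median of -0.34 (camera adjusted p = 0.196). Of 17 nitrogenase genes, 2 were higher and 1 lower (0 adjusted over the list alone), with a median of -0.24 (camera adjusted p = 0.918). The highest genes were asl2052 (7.12 ± 0.27), all4312 (5.29 ± 0.24), ald (4.65 ± 0.17), all7607 (4.49 ± 0.78) and all7619 (4.48 ± 0.60). The value of ntcA was -0.66 ± 0.12, adjusted p = 0.00137, and of nblA 4.36 ± 0.22. Of 5882 genes, limma called 889 higher and 1137 lower, so that 43.9% of the calls were higher. This share ran from 22.4% with the array median to 67.8% with the 75th percentile over probes detected on all arrays over the other scalings, and the median of all genes from -0.39 to 0.11. In each scaling, all of the 681 called genes at least 2-fold apart kept their direction, and a fixed slide block gave calls for 39.0% of genes.

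By 12 h (2 arrays against 2) the mutant had lower transcripts for photosystem II, phycobilisomes and ribosomes. The 21 phycobilisome genes included 21 lower, at a median of -4.53 (camera adjusted p = 1.06e-15, adjusted p = 0.183 with an estimated correlation). The 23 ribosomal protein genes included 23 lower, at a median of -2.66 (camera adjusted p = 2.58e-15, adjusted p = 0.183 with an estimated correlation). ATP synthase genes had a median of -2.55, with 9 lower of 9 (camera adjusted p = 2.61e-07, adjusted p = 0.183 with an estimated correlation). Photosystem II genes had a median of -2.11, with 13 lower and 1 higher of 14 (camera adjusted p = 1.34e-07, adjusted p = 0.183 with an estimated correlation). Photosystem I genes had a median of -1.54, with 8 lower of 8 (camera adjusted p = 7.52e-05, adjusted p = 0.267 with an estimated correlation). Their median was 0.038 to 0.12 with quantile normalizations or the authors' deposited values. Nitrogenase genes had a median of -0.10, against 0.050 with a common floor after scaling, with 6 lower and 3 higher of 17 (camera adjusted p = 0.701). Of 18 glycolipid genes, 11 were lower and 1 higher, with a median of -0.77 (camera adjusted p = 0.102). The 9 heterocyst respiration genes included 7 higher, at a median of 1.27 (camera adjusted p = 0.0245, adjusted p = 0.528 with an estimated correlation). The highest genes included asl2052 (5.70 ± 0.27), all2747 (4.86 ± 0.14) and all4312 (4.83 ± 0.24), and the lowest pecA (-7.12 ± 0.24), pecC (-6.80 ± 0.26) and asr1328 (-6.80 ± 0.15). The test called 1645 of 5882 genes higher and 1868 lower, 46.8% of the calls being higher. Over the other scalings the share lay from 11.6% with the array median to 78.0% with the 75th percentile over probes detected on all arrays, and the median of all genes from -0.79 to 0.52. Direction was kept in each scaling by 1600 or more of the 1637 called genes at least 2-fold apart, and with a random slide block 41.1% of genes were called.

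At 24 h (2 arrays against 2) the mutant's phycobilisome transcripts were far lower, and the slope on level was -0.25. Of 21 phycobilisome genes, 21 were lower, with a median of -5.51 (camera adjusted p = 3.65e-15, adjusted p = 0.254 with an estimated correlation). The lowest were pecB (-10.17 ± 0.34), pecA (-9.97 ± 0.24), pecC (-8.75 ± 0.26) and cpcC (-8.18 ± 0.35). The 9 ATP synthase genes included 9 lower, at a median of -3.63 (camera adjusted p = 2.19e-07, adjusted p = 0.254 with an estimated correlation). The 8 photosystem I genes included 8 lower, at a median of -2.70 (camera adjusted p = 4.34e-06, adjusted p = 0.254 with an estimated correlation). The 14 photosystem II genes included 13 lower and 1 higher, at a median of -2.27 (camera adjusted p = 1.40e-06, adjusted p = 0.254 with an estimated correlation). Of 23 ribosomal protein genes, 23 were lower, with a median of -2.50 (camera adjusted p = 2.52e-13, adjusted p = 0.254 with an estimated correlation). Dev exporter genes had a median of 1.75, with 3 higher of 3 (camera adjusted p = 0.0695). Of 9 heterocyst respiration genes, 7 were higher, with a median of 1.21 (camera adjusted p = 0.0695). Nitrogen assimilation genes had a median of 0.91, against -0.050 with the array median, with 9 higher (10 adjusted over the list alone) and 4 lower of 20 (camera adjusted p = 0.13). Its urea transporter gene urtA was at 2.83 ± 0.20. The 17 nitrogenase genes included 6 higher and 6 lower, at a median of -0.28 (camera adjusted p = 0.657). The highest genes included asl2052 (7.21 ± 0.27), fabG all0968 (6.44 ± 0.34), all4236 (5.39 ± 0.25) and all2747 (5.16 ± 0.14). The signs of hetR, hetZ, hetP and glnA at 12 h or 24 h, and of hetC and nirA at 24 h, turned with the scaling or with the probe used for the gene, so no direction is given for them. Among 5882 genes, 2017 were called higher and 1903 lower (51.5% higher). Other scalings gave shares from 12.4% with the array median to 81.1% with the 75th percentile over probes detected on all arrays, and moved the median of all genes from -0.89 to 0.84. A random slide block gave calls for 51.0% of genes, and 2102 or more of the 2149 called genes at least 2-fold apart kept their direction in each scaling.

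From 12 h to 24 h within slide 2, the mutant's transcripts for light harvesting went on falling. Phycobilisome genes had a median of -1.0, with 16 lower (17 adjusted over the list alone) of 21 (camera adjusted p = 1.17e-09, adjusted p = 0.24 with an estimated correlation). Of 8 photosystem I genes, 8 were lower, with a median of -1.24 (camera adjusted p = 4.26e-09, adjusted p = 0.214 with an estimated correlation).

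In ammonium medium (2 arrays of the mutant against 3 of WT), the strains already differed. The gene hetZ, which takes part in differentiation, was lower in the mutant (-3.34 ± 0.15, adjusted p = 6.08e-09), at 1.83 ± 0.15 (SD, n = 3) in WT and -1.51 ± 0.24 (SD, n = 2) in the mutant, as was its neighbour asr0098 (-4.78 ± 0.19). Other low genes were alr7326 (-4.60 ± 0.16), alr7300 (-4.32 ± 0.24) and all7002 (-3.95 ± 0.13) of the pCC7120alpha plasmid. The highest were alr4637 (9.92 ± 0.25), alr0444 (8.55 ± 0.19), all2655 (8.45 ± 0.29), asr4638 (8.13 ± 0.20) and all2638 (7.24 ± 0.24). The 18 differentiation regulator genes included 6 lower and 3 higher, at a median of -0.29, against 0.24 with the array median (camera adjusted p = 0.0157, adjusted p = 0.502 with an estimated correlation). The 20 nitrogen assimilation genes included 6 lower and 4 higher, at a median of -0.14, against 0.39 with the array median (camera adjusted p = 0.0868). Of 19 polysaccharide genes, 11 were higher, with a median of 0.60 (camera adjusted p = 0.0145, adjusted p = 0.618 with an estimated correlation). The 21 phycobilisome genes included 17 higher (19 adjusted over the list alone), at a median of 0.58 (camera adjusted p = 0.000354, adjusted p = 0.556 with an estimated correlation). Ribosomal protein genes had a median of 0.64, with 22 higher (23 adjusted over the list alone) of 23 (camera adjusted p = 2.08e-06, adjusted p = 0.556 with an estimated correlation). Of 9 ATP synthase genes, 9 were higher, with a median of 0.91 (camera adjusted p = 0.00018, adjusted p = 0.556 with an estimated correlation). Of 14 photosystem II genes, 8 were higher (9 adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.0145, adjusted p = 0.556 with an estimated correlation). Their median was -0.068 to -0.044 with quantile normalizations or the authors' deposited values. The signs of rbcL, psbB and alr3710 turned with the scaling, and that of nifH without WT replicate 3. Without replicate 1 of the mutant at 0 h, 1429 genes were called. Of 5882 genes, 1533 were called higher and 855 lower (64.2% higher). Other scalings gave 33.4% with the 75th percentile over probes detected on all arrays to 90.6% with the array median, and medians of all genes from -0.063 to 0.70. A fixed slide block called 46.1% of genes, and all 647 called genes at least 2-fold apart kept their direction in each scaling.

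**Figure D2:**
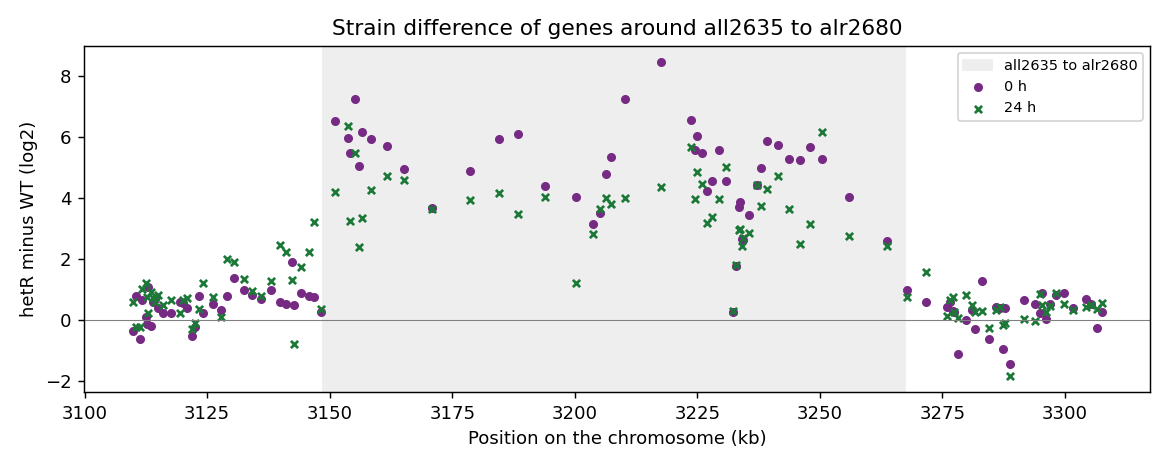
Difference between the hetR mutant and WT (log2) of each gene against its position on the chromosome (kb) at 0 h (circles) and 24 h (crosses), with all2635 to alr2680 shaded. At 0 h, 45 of the 46 genes in the shaded stretch were called higher in the mutant, with a median of 5.14, and 30 of them were not well above background on any WT 0 h array.

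**Figure D3:**
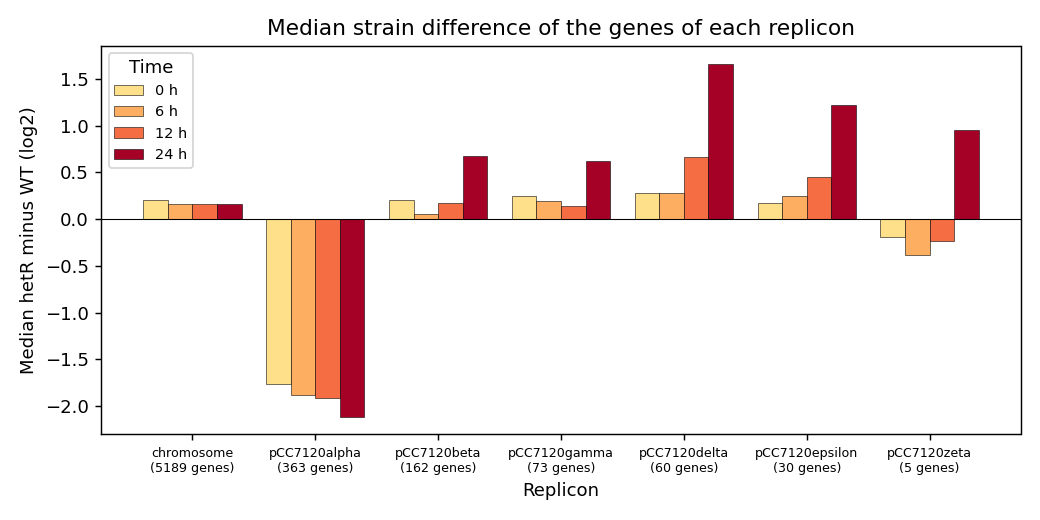
Median difference between the hetR mutant and WT (log2) over the genes of each replicon at 0, 6, 12 and 24 h (bars), with the number of genes under each name. Genes of pCC7120alpha had medians of -1.77, -1.88, -1.91 and -2.11.

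The difference of response, positive where the WT change lay above that of the mutant, tests which part of the response depends on the strain. At 6 h it was largest for envelope polysaccharide genes. Polysaccharide genes had a median of 6.13, with 19 higher of 19 (camera adjusted p = 6.36e-47, adjusted p = 0.0113 with an estimated correlation). They included alr2827 (8.59 ± 0.27), rfbF (8.33 ± 0.29) and lhgO (8.28 ± 0.31). The 3 Dev exporter genes included 3 higher, at a median of 1.41 (camera adjusted p = 0.000138, adjusted p = 0.0779 with an estimated correlation). Of 18 differentiation regulator genes, 6 were higher (7 adjusted over the list alone) and 1 lower (2 adjusted over the list alone), with a median of 0.27 (camera adjusted p = 0.0288, adjusted p = 0.186 with an estimated correlation). Among them, hetP was at 3.85 ± 0.16, adjusted p = 2.77e-08 and ntcA at 2.13 ± 0.16, adjusted p = 6.26e-06. The 23 ribosomal protein genes included 18 higher (22 adjusted over the list alone), at a median of 1.00 (camera adjusted p = 4.65e-17, adjusted p = 0.186 with an estimated correlation). Of 21 phycobilisome genes, 4 were higher (11 adjusted over the list alone), with a median of 0.73 (camera adjusted p = 1.60e-06, adjusted p = 0.334 with an estimated correlation). In the main scaling part of these 2 came from the mutant's higher start. On its 0 h arrays ribosomal proteins were at 0.73 and 0.54 and phycobilisomes at 0.68 and 0.45, relative to WT. Of 17 nitrogenase genes, 3 were higher, with a median of 0.62, against -0.0044 with the authors' deposited values (camera adjusted p = 0.0138, adjusted p = 0.651 with an estimated correlation). The lowest genes were all3035 (-2.35 ± 0.29), all3526 (-2.14 ± 0.56) and patA (-2.05 ± 0.34). Without replicate 2 of the mutant at 6 h, 273 genes were called. Of 5882 genes, limma called 290 higher and 197 lower, so that 59.5% of the calls were higher. This share ran from 12.2% with the authors' deposited values to 93.6% with the array median over the other scalings, and the median of all genes from -0.25 to 0.45. In each scaling, 285 or more of the 287 called genes at least 2-fold apart kept their direction, and a fixed slide block gave calls for 10.8% of genes.

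At 12 h the strains parted in nitrogenase and glycolipid transcripts. Nitrogenase genes had a median of 5.41, with 17 higher of 17 (camera adjusted p = 1.17e-27, adjusted p = 0.0323 with an estimated correlation). Glycolipid genes had a median of 5.05, with 17 higher and 1 lower of 18 (camera adjusted p = 3.79e-22, adjusted p = 0.0323 with an estimated correlation). The 19 polysaccharide genes included 19 higher, at a median of 4.10 (camera adjusted p = 3.08e-28, adjusted p = 0.0307 with an estimated correlation). Of 3 Dev exporter genes, 3 were higher, with a median of 3.81 (camera adjusted p = 3.77e-06, adjusted p = 0.0307 with an estimated correlation). Heterocyst respiration genes had a median of 3.96, with 9 higher of 9 (camera adjusted p = 8.34e-11, adjusted p = 0.0859 with an estimated correlation). The differences were largest for nifD (8.81 ± 0.64), nifK (8.47 ± 0.34), hesB (8.02 ± 0.28) and asl1434 (6.91 ± 0.29), and lowest for alr7029 (-2.93 ± 0.49), alr4456 (-2.74 ± 0.24) and all8519 (-2.56 ± 0.18). Pentose phosphate genes had a median of 0.97, with 5 higher of 5 (camera adjusted p = 2.10e-05, adjusted p = 0.0882 with an estimated correlation). Phycobilisome genes had a median of 0.93, with 12 higher (14 adjusted over the list alone) of 21 (camera adjusted p = 1.60e-07, adjusted p = 0.251 with an estimated correlation). ATP synthase genes had a median of 0.80, with 7 higher (9 adjusted over the list alone) of 9 (camera adjusted p = 1.32e-05, adjusted p = 0.251 with an estimated correlation). Of 23 ribosomal protein genes, 8 were higher (13 adjusted over the list alone), with a median of 0.50, against -0.023 with normexp with quantile normalization and -0.028 with the authors' deposited values (camera adjusted p = 9.54e-07, adjusted p = 0.352 with an estimated correlation). Photosystem II genes had a median of 0.33, against -0.18 with normexp with quantile normalization and -0.11 with quantile normalization and -0.19 with the authors' deposited values, with 2 higher (4 adjusted over the list alone) of 14 (camera adjusted p = 0.0161, adjusted p = 0.429 with an estimated correlation). Levels were close in part of these lists. Relative to WT at 0 h, ATP synthase medians at 12 h were -1.71 and -1.81 in WT and -1.61 and -1.74 in the mutant. The mutant started at 0.97 and 0.84. For ribosomal proteins these were -2.15 and -2.17, -1.99 and -2.01 and 0.73 and 0.54. For photosystem II they were -1.69 and -1.76, -1.69 and -1.76 and 0.58 and 0.28. In the main scaling the mutant's higher start made much of these 3 differences, but that of photosystem II turned in others. Without replicate 2 of the mutant at 12 h, 606 genes were called. The test called 560 of 5882 genes higher and 400 lower, 58.3% of the calls being higher. Over the other scalings the share lay from 24.0% with the authors' deposited values to 95.9% with the array median, and the median of all genes from -0.18 to 0.53. Direction was kept in each scaling by 541 or more of the 558 called genes at least 2-fold apart, and with a fixed slide block 20.3% of genes were called.

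At 24 h nitrogenase had the largest median difference of the 15 lists, and the responses of light harvesting, ATP synthase and ribosomal protein genes lay below those of WT in the mutant. Over all genes the difference rose with mean level, at a slope of 0.10. Camera did not match lists on level, so the part of a list's difference that goes with level was not tested. The 17 nitrogenase genes included 17 higher, at a median of 5.52 (camera adjusted p = 1.34e-17, adjusted p = 0.104 with an estimated correlation). They included nifK (9.61 ± 0.34), nifD (8.26 ± 0.64) and nifW (7.18 ± 0.29). The gene all3999, beside the iron stress gene isiA, was at 7.62 ± 0.40. Of 19 polysaccharide genes, 19 were higher, with a median of 3.38 (camera adjusted p = 4.81e-16, adjusted p = 0.104 with an estimated correlation). The 9 heterocyst respiration genes included 9 higher, at a median of 3.32 (camera adjusted p = 1.40e-06, adjusted p = 0.142 with an estimated correlation). The 18 glycolipid genes included 17 higher and 1 lower, at a median of 2.81 (camera adjusted p = 2.48e-10, adjusted p = 0.117 with an estimated correlation). Dev exporter genes had a median of 1.55, with 3 higher of 3 (camera adjusted p = 0.0106, adjusted p = 0.117 with an estimated correlation). The 9 ATP synthase genes included 9 higher, at a median of 2.58 (camera adjusted p = 1.81e-10, adjusted p = 0.104 with an estimated correlation). The 21 phycobilisome genes included 21 higher, at a median of 2.29 (camera adjusted p = 1.87e-14, adjusted p = 0.104 with an estimated correlation). Ribosomal protein genes had a median of 2.06, with 23 higher of 23 (camera adjusted p = 4.51e-19, adjusted p = 0.104 with an estimated correlation). Photosystem I genes had a median of 1.17, with 8 higher of 8 (camera adjusted p = 2.02e-05, adjusted p = 0.163 with an estimated correlation). The 14 photosystem II genes included 10 higher and 1 lower, at a median of 1.11 (camera adjusted p = 0.000167, adjusted p = 0.163 with an estimated correlation). In the main scaling part of this came from the mutant's higher start (0.58 and 0.28 at 0 h), whose sign turned in others. Medians at 24 h were -1.29 and -1.52 in WT and -1.68 and -1.71 in the mutant. The 5 pentose phosphate genes included 5 higher, at a median of 1.35 (camera adjusted p = 4.34e-05, adjusted p = 0.104 with an estimated correlation). Of 20 nitrogen assimilation genes, 7 were lower and 6 higher, with a median of -0.67, against 0.0065 with the array median (camera adjusted p = 0.0984). The most negative differences were those of ntrB alr2878 (-3.56 ± 0.41), urtA (-3.54 ± 0.27), cmpA (-3.52 ± 0.54), all1950 (-3.36 ± 0.21) and cmcC (-3.27 ± 0.36). Among 5882 genes, 1130 were called higher and 945 lower (54.5% higher). Other scalings gave shares from 24.0% with the 75th percentile over probes detected on all arrays to 92.2% with the array median, and moved the median of all genes from -0.42 to 0.66. A fixed slide block gave calls for 37.5% of genes, and 1088 or more of the 1097 called genes at least 2-fold apart kept their direction in each scaling.

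**Figure D4:**
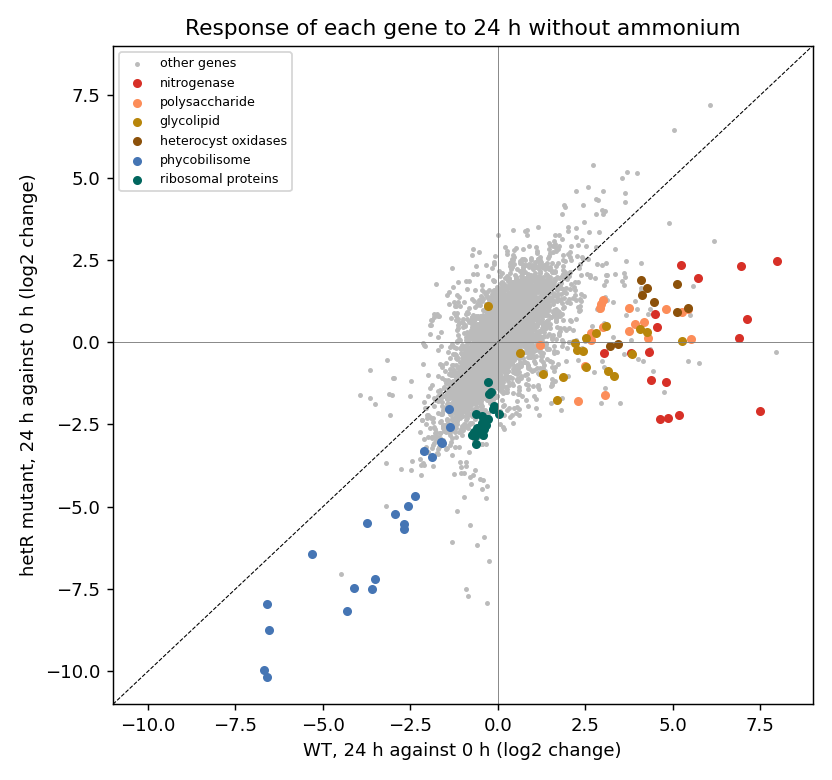
Log2 change of each gene from 0 h to 24 h in WT (horizontal axis) and the hetR mutant (vertical axis), with 6 gene lists in colour and a dashed line of equal change. The median difference of response was 5.52 for nitrogenase and 2.29 for phycobilisome genes.

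The effect of giving back ammonium was measured with 1 array before and 1 array 8 h after addition of 10 mM ammonium, with no replicates and no test. Heterocyst and assimilation transcripts were lower after addition, the median difference being -2.28 (percentile 0) for polysaccharide genes, -1.97 (percentile 0) for nitrogenase, -1.68 (percentile 0) for heterocyst respiration and -1.26 (percentile 0) for nitrogen assimilation. Photosystem II was at 0.85 (percentile 99.96) and photosystem I at -0.28 (percentile 0.46). The percentile places each median among 10000 random lists matched on mean level and describes these arrays alone. The lowest genes lay around isiA, for an iron stress chlorophyll protein, with isiA at -7.13, and all4000 and all4003 at least 80.2-fold and 139-fold lower against the detection limit. The highest included all0458, all0457 and all0615, at least 56.5-fold, 33.9-fold and 35.9-fold higher against the detection limit. Of 5279 genes, 300 were at least 2-fold higher and 485 lower. This was 38.2% higher, and other scalings gave 29.9% with the 75th percentile over probes detected on all arrays to 48.9% with normexp with quantile normalization.

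WT growing without combined nitrogen (1 array) was set against the 3 WT arrays in ammonium medium, with no test and with slide and group not to be told apart. Nitrogenase was at 5.66 (percentile 100), heterocyst respiration at 5.05 (percentile 100), polysaccharide at 3.75 (percentile 100) and phycobilisome at -2.41 (percentile 0). The highest genes included nifH, nifD and nifK, at least 153-fold, 111-fold and 74.8-fold higher against the detection limit. Among the lowest were pecC at -6.63 and pecE at least 27.6-fold lower. Of 5296 genes, 505 were at least 2-fold higher and 357 lower. The higher share was 58.6%, and other scalings gave 45.6% with the array median to 77.1% with the 75th percentile over probes detected on all arrays.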

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

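The tests on genes of pCC7120alpha and on all2635 to alr2680 were chosen after the results were seen, as was the test of signal distributions on dim and bright genes, while the test of slides on these last genes was set before.

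The strains' responses at 6 h differed in 487 genes by limma's test of the difference itself. The median difference was 0.62 for nitrogenase genes, 6.13 for polysaccharide genes, 1.41 for Dev exporter genes, 0.27 for differentiation regulator genes, 0.73 for phycobilisome genes, 0.43 for photosystem II genes, 0.58 for ATP synthase genes and 1.00 for ribosomal protein genes. Other settings turned the sign of nitrogenase at -0.0044 with the authors' deposited values. The highest genes were at 8.59 for alr2827, 8.33 for rfbF, 8.28 for lhgO, 7.78 for alr2831 and 7.37 for alr2828. The lowest were at -2.35 for all3035, -2.14 for all3526, -2.05 for patA, -2.03 for all2263 and -2.01 for alr4740. At 6 h the mutant's photosystem II and ATP synthase were not below WT. Relative to WT at 0 h, photosystem II was at -0.72 and -0.79 in WT and -0.65 and -0.54 in the mutant. ATP synthase was at -0.93 and -0.82 and -0.73 and -0.61. In the main scaling both differences came from the mutant's higher start (0.58 and 0.28, turned in others, and 0.97 and 0.84).

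At 12 h the responses of the strains differed in 960 genes by the same test. The median difference was 5.41 for nitrogenase genes, 5.05 for glycolipid genes, 4.10 for polysaccharide genes, 3.81 for Dev exporter genes, 3.96 for heterocyst respiration genes, 0.93 for phycobilisome genes, 0.33 for photosystem II genes, 0.80 for ATP synthase genes, 0.97 for pentose phosphate genes and 0.50 for ribosomal protein genes. Other settings turned the signs of photosystem II (to -0.19) and ribosomal protein (to -0.028), as given above. The highest genes were at 8.81 for nifD, 8.47 for nifK, 8.02 for hesB, 6.91 for asl1434 and 6.85 for fdxH. The lowest were at -2.93 for alr7029, -2.74 for alr4456, -2.56 for all8519, -2.46 for ppsA at 3808410 to 3810341 and -2.43 for all0565.

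By 24 h responses differed in 2075 genes, and over all genes the difference rose with level (slope 0.10). The median difference was 5.52 for nitrogenase genes, 2.81 for glycolipid genes, 3.38 for polysaccharide genes, 1.55 for Dev exporter genes, 3.32 for heterocyst respiration genes, 2.29 for phycobilisome genes, 1.11 for photosystem II genes, 1.17 for photosystem I genes, 2.58 for ATP synthase genes, 1.35 for pentose phosphate genes and 2.06 for ribosomal protein genes. The highest genes were at 9.61 for nifK, 8.26 for nifD, 7.62 for all3999, 7.39 for asl1434 and 7.18 for nifW. The lowest were at -3.56 for ntrB alr2878, -3.54 for urtA, -3.52 for cmpA, -3.36 for all1950 and -3.27 for cmcC.

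Genes of the plasmid pCC7120alpha were lower in the mutant than in WT, 289 of its 363 genes at 0 h, with medians of -1.77, -1.88, -1.91 and -2.11 at 0, 6, 12 and 24 h. Over 4 scalings the median least far from 0 was -1.24, but most shift all genes alike and test little. A slide effect is argued against by medians of -1.77 or lower on both slide 1 and slide 2. A lower dose of the whole plasmid may account for it, but the spread of the differences was 1.84 times that of chromosomal genes, between the limits set for and against that reading, while medians of 50 kb windows ran from -2.57 to -1.70. Loss of hetR function and other differences between the 2 strains were not separated and stay open.

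The 46 genes from all2635 to alr2680, at 3148687 to 3267437 on the chromosome, had a median of 5.14 above WT in the mutant at 0 h, and 45 of them were called higher. A first test by detection did not decide, because 100% of the 46 genes were well above background on both mutant 0 h arrays and 78.3% on both WT 24 h arrays. Over 4 scalings the lowest median was 4.91, again a weak test. A difference confined to ammonium medium is argued against by a median of 3.77 at 24 h, and of 3.43 over the 36 members well above background on all 24 h arrays. Whether nitrogen status changed its size cannot be told, because 30 of the 46 were not well above background on any WT 0 h array. The median member kept at least 78.0% of its difference at 6, 12 and 24 h, but with signals raised to the highest detection limit of the arrays, which makes differences smaller, the medians were 3.05 at 0 h and 0.94 at 24 h. Whether loss of hetR function or another difference between the strains may account for it was not tested.

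After nitrogen removal dim genes tended to be higher and bright genes lower, with a slope of log2 change on level of -0.15 for WT at 24 h, -0.17 for WT at 12 h and -0.25 for the mutant at 24 h. With quantile normalization the WT slope at 24 h was -0.061 in place of -0.15, so that different distributions of signals between arrays may account for part of it. Scaling by 1 factor per array cannot make a slope. A slide effect may account for part of it and cannot be told apart from the change, as the slopes were -0.027 within slide 3 (WT 8 h), -0.045 and -0.0048 within slide 1 (6 h in WT and the mutant), -0.10 and 0.021 within slide 2 (12 h to 24 h in the mutant and WT) and 0.0087 within slide 4 (ammonium addition). The nitrogen step itself stays among the open explanations. The difference of response at 24 h had a slope of 0.10.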

How the results depend on the processing

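The scaling by probes detected on all arrays, the common floor, the fit without slide 3, the universe of all features for camera and camera on the 8 h and 0 h arrays alone were chosen after the data were seen. Over all alternatives, 6404 of 6879 values of named genes kept their direction and their side of the threshold, 290 lost the call, 128 gained it and 57 turned. For gene lists these were 1777, 196, 82 and 30 of 2085. Camera called 113 of 165 list tests with the preset correlation and 10 of these with an estimated one. With all features as its universe, the 113 calls were kept and 5 were added. The cause was not tested for any value below, unless the setting itself leaves out samples or tightens the threshold. For genes below detection at 0 h the log2 changes rest on signals near background, and only folds written as at least are lower bounds.

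Calls are given as percent of the 5882 genes of the main fit, and untested comparisons as genes at least 2-fold apart. With a 2-fold threshold added, calls were 11.4% for WT 6 h, 23% for WT 12 h, 19.5% for WT 24 h, 11.6% for mutant 6 h, 27.8% for mutant 12 h, 36.5% for mutant 24 h, 11% for strain 0 h, 4.88% for difference 6 h, 9.49% for difference 12 h, 18.7% for difference 24 h and 14.5% for WT 8 h. Fits of the groups compared alone gave 18.5% for WT 6 h, 14.3% for strain 0 h, 2.45% for difference 6 h, 8.89% for difference 12 h and 4.23% for WT 8 h. Normexp with quantile normalization gave 31.7% for difference 6 h, 28.4% for difference 12 h, 49.8% for WT 8 h, 362 genes for ammonium addition and 366 genes for steady state. The authors' deposited values gave 31% for difference 6 h, 28.1% for difference 12 h, 49.3% for WT 8 h, 407 genes for ammonium addition and 411 genes for steady state. The array median gave 72% for strain 0 h and 25.4% for difference 12 h. The random slide block gave 34.2% for WT 24 h. With all arrays and the main setting these were 38% for WT 6 h, 56.5% for WT 12 h, 53.2% for WT 24 h, 32.4% for WT 8 h, 34.4% for mutant 6 h, 59.7% for mutant 12 h, 66.6% for mutant 24 h, 40.6% for strain 0 h, 8.28% for difference 6 h, 16.3% for difference 12 h, 35.3% for difference 24 h, 785 genes for ammonium addition and 862 genes for steady state. Apart from single arrays left out, the other counts for these comparisons stayed within 1.5 times of the main ones. For steps within the time course, calls for WT from 12 h to 24 h went from 620 to 227 genes with the array median, 322 with the brightest probe and 940 with a common floor. For the mutant from 12 h to 24 h they went from 1439 to 826 with the brightest probe, and for WT from 6 h to 12 h from 2972 to 1563 with the random slide block.

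Leaving out 1 array at a time gave ranges of WT 6 h 25.9% to 39.4%, WT 12 h 44.4% to 59.8%, WT 24 h 39.1% to 57.8%, WT 8 h 27.8% to 40.6%, mutant 6 h 24.7% to 30.8%, mutant 12 h 48.4% to 53.2%, mutant 24 h 58% to 61.1%, strain 0 h 24.3% to 46.1%, difference 6 h 4.64% to 10.8%, difference 12 h 10.3% to 20.3% and difference 24 h 25.5% to 37.5%. Counts moved by over 1.5 times without mutant 0 h replicate 1 (strain 0 h 24.3%, difference 6 h 5.10%, difference 12 h 10.5%), WT 6 h replicate 2 (difference 6 h 4.68%), mutant 6 h replicate 2 (difference 6 h 4.64%), WT 12 h replicate 2 (difference 12 h 10.6%) and mutant 12 h replicate 2 (difference 12 h 10.3%). From 12 h to 24 h, leaving out each array moved them so, to 392, 209, 216 and 236 genes in WT and 619, 879, 916 and 514 in the mutant without replicates 1 and 2 at 12 h and 1 and 2 at 24 h. The strain difference of nifH at 0 h ran from -0.88 to 0.48 and turned without WT 0 h replicate 3. A group left with 1 array was assumed to vary like the others.

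The replicate block gave calls of WT 6 h 39.3%, WT 12 h 59.9%, WT 24 h 57.5%, WT 8 h 40%, mutant 6 h 38.8%, mutant 12 h 63.9%, mutant 24 h 70.4%, strain 0 h 46.3%, difference 6 h 10.3%, difference 12 h 19.7% and difference 24 h 36.9%, and turned nifH (strain 0 h 0.48). The deviations of same-numbered arrays correlated at -0.23 to 0.47 over 28 pairs of groups, 4 of them over 0.1. The highest were WT 0.47 and mutant 0.15 between 12 h and 24 h, so that these arrays deviated together by number, while most pairs of groups did not and the numbers were not taken to pair the samples. With the replicate block, WT from 12 h to 24 h had 838 calls. No paired analysis was possible for the 2 untested comparisons because they come from no test.

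Values are log2 medians for lists. Signs that turned with normexp with quantile normalization were those of hetP (mutant 6 h 0.10, mutant 12 h 0.030), hetR (mutant 24 h 0.20), hetZ (mutant 24 h -0.12, difference 12 h 0.47), glnA (mutant 24 h 0.91), rbcL (strain 0 h -0.16, difference 12 h -0.091), psbB (strain 0 h -0.23), nitrogenase genes (WT 6 h -0.058), ribosomal protein genes (WT 24 h 0.061, difference 12 h -0.023), photosystem I genes (mutant 6 h 0.091, mutant 12 h 0.10) and photosystem II genes (strain 0 h -0.046, difference 12 h -0.18). With quantile normalization alone, signs turned for hetR (mutant 24 h 0.37), hetP (mutant 24 h -0.39), glnA (mutant 24 h 1.21), alr3710 (strain 0 h -0.25), rbcL (strain 0 h -0.081), psbB (strain 0 h -0.15), ribosomal protein genes (WT 24 h 0.16), photosystem I genes (mutant 6 h 0.071, mutant 12 h 0.038), chaperone genes (mutant 12 h 0.038) and photosystem II genes (strain 0 h -0.044, difference 12 h -0.11). Use of the array median turned hetR (mutant 12 h -0.39), hetZ (mutant 12 h -0.17, mutant 24 h -0.57), devA (mutant 12 h -0.089), glnA (mutant 12 h -0.61), hetP (mutant 24 h -0.85), heterocyst respiration genes (mutant 6 h -0.024), differentiation regulator genes (mutant 12 h -0.29, strain 0 h 0.24) and nitrogen assimilation genes (mutant 24 h -0.050, strain 0 h 0.39, difference 24 h 0.0065). Signs that turned with the authors' deposited values were those of hetP (mutant 6 h 0.13, mutant 12 h 0.066), hetR (mutant 24 h 0.20), hetZ (mutant 24 h -0.10, difference 12 h 0.46), glnA (mutant 24 h 0.90), rbcL (strain 0 h -0.17, difference 12 h -0.11), psbB (strain 0 h -0.24), nitrogenase genes (WT 6 h -0.060, difference 6 h -0.0044), ribosomal protein genes (WT 24 h 0.065, difference 12 h -0.028), photosystem I genes (mutant 6 h 0.11, mutant 12 h 0.12) and photosystem II genes (strain 0 h -0.068, difference 12 h -0.19). With the brightest probe of a gene, signs turned for hetC (WT 6 h -0.14, mutant 24 h 1.26, difference 24 h -0.21, WT 8 h -0.019), nirA (WT 6 h -0.95, WT 12 h -0.34, WT 24 h -1.83, mutant 6 h -1.63, mutant 12 h -2.88, mutant 24 h -3.41, WT 8 h -0.85), hetR (mutant 12 h -0.045) and hetZ (mutant 12 h -0.52, mutant 24 h -0.90, difference 12 h 0.98, difference 24 h 0.48). Use of the 75th percentile over probes detected on all arrays turned hetR (mutant 24 h 0.49), glnA (mutant 24 h 0.60) and chaperone genes (WT 24 h 0.0036, mutant 12 h 0.19). Signs that turned with a common floor after scaling were those of hetZ (mutant 12 h -0.093, mutant 24 h -0.26, difference 12 h 0.54), hetC (mutant 24 h 0.42, difference 24 h -0.071) and nitrogenase genes (mutant 12 h 0.050). With the fixed slide block, signs turned for nifH (strain 0 h 0.48). Leaving out slide 3 turned nifH (strain 0 h 0.48).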

Other observations

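The genes and replicons in this part were chosen after their values were seen. At 24 h the responses of isiA, whose product binds chlorophyll under iron limitation, of all4003 and of fldA, the flavodoxin gene, differed between strains. In the mutant they were at -7.70, adjusted p = 4.29e-09, -6.17, adjusted p = 4.08e-09 and -6.08, adjusted p = 7.01e-10, and in WT at -0.86, adjusted p = 0.0342, -0.59, adjusted p = 0.0626 and -1.32, adjusted p = 7.46e-05. The differences of response were 6.84, adjusted p = 1.14e-06, 5.58, adjusted p = 8.74e-07 and 4.76, adjusted p = 3.16e-07. At 6 h isiA in WT was at -3.22, adjusted p = 7.48e-06.

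Some genes changed strongly in both strains. The small gene asl2052 rose by 8.08, adjusted p = 4.34e-10 in WT and by 7.12, adjusted p = 6.37e-09 in the mutant at 6 h, and all4312, for a response regulator, by 4.62, adjusted p = 1.82e-08 and 5.29, adjusted p = 2.35e-08. On pCC7120beta, all7607 rose by 4.53, adjusted p = 0.000445 in WT and 4.49, adjusted p = 0.00104 in the mutant at 6 h. The small gene asr1328 was at -6.33, adjusted p = 8.99e-11 and -6.66, adjusted p = 1.82e-10. The tests of the difference at 6 h gave 0.95, adjusted p = 0.145 for asl2052, -0.68, adjusted p = 0.245 for all4312, 0.047, adjusted p = 0.984 for all7607 and 0.33, adjusted p = 0.373 for asr1328.

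In the mutant alr4637 and asr4638 were far above WT in ammonium medium, at 9.92, adjusted p = 1.19e-10 and 8.13, adjusted p = 1.05e-10. The median difference of the mutant from WT over 4 plasmids lay near that of the chromosome at 0 h and above it at 24 h. At 0 h and 24 h they were 0.27 and 1.66 over 60 genes of pCC7120delta, 0.18 and 1.22 over 30 of pCC7120epsilon, 0.20 and 0.68 over 162 of pCC7120beta and 0.25 and 0.62 over 73 of pCC7120gamma, against 0.20 and 0.16 over 5189 genes of the chromosome. The 5 genes of pCC7120zeta were at -0.19 and 0.95. At 6 h and 12 h pCC7120delta was at 0.28 and 0.67. The other scalings were not applied to these medians.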
